A study of Mus musculus with 6 samples.

How the data were processed

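Transcript 3′ ends were measured in 6 libraries of the mouse KPr lung cancer line, 3 parental and 3 reactivated. Per the labels' protocols, total RNA was extracted from cell pellets with a column kit, and 100 ng entered Lexogen's QuantSeq 3′ library preparation for Illumina sequencing. This chemistry gives about 1 read position per transcript, near the polyadenylation site, so levels need no correction for gene length. A gene with an alternative 3′ end outside the annotation can be undercounted.

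The deposited table holds whole-number counts per Ensembl gene in 6 columns, not scaled between libraries. The submitters' processing notes name Bowtie2, RSEM 1.2.31, DESeq2 and the mouse build mm10, with no role or order. If RSEM made the deposited counts, they are its estimates rounded to whole numbers, which the file does not say. Reads that map to several genes would then be shared between near-identical genes. The annotation release and the strand setting are not given in the sources used here. Genes that overlap on either strand, and close paralogs, are therefore uncertain. Of the genes named in the text, B2m, Ccna2, Ccnd1, Ddit3, Ddx3y, Fgf13, Fgf2, Fgfr2, Fosl1, Gas6, Gpc1, Gsr, Kif15, Kras, Loxl2, Ltbp3, Nusap1, Pclaf, S100a4, Tgfb3 and Tgfbr3 overlap another annotated gene with counts, and their values are uncertain for this reason. Paralogs were not searched for. Libraries held 24955652 to 29441082 counts, and 1 CPM, after scaling, stands for 24.7 to 30.9 counts. No single gene took more than 2.49% of a library. All columns were used.

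Gene symbols and coordinates (1-based) came from a GENCODE mouse annotation of GRCm38, the assembly that mm10 names. Of the 51789 gene identifiers, 51596 matched a symbol. Columns were matched to the labels by group and replicate number. No library pair of either group was identical or agreed within sampling noise: the closest pair, reactivated 1 and 3, differed by a chi-square of 7.27 per gene on 1 degree of freedom over 12795 genes with at least 50 counts.

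The main test was edgeR's (4.0.16, R 4.3.3) quasi-likelihood test of the deposited counts on group alone. It used TMM scaling, genes kept by filterByExpr (minimum count 10) and Benjamini-Hochberg adjustment over the 14365 genes tested, with a threshold of 0.05. CPM are TMM-scaled, means are given ± SD over 3 libraries, and the SE of a log2 fold change is approximated as its size over the square root of the F statistic. A total of 33 gene lists were fixed before the data were examined. The 31 with at least 5 measured members were tested with camera (limma 3.58.1) on log2 CPM, two-sided, with a preset correlation of 0.01. Fibroblast markers had 4 measured members, and mitochondrially encoded genes were not analysed here. "Adjusted over the list alone" means Benjamini-Hochberg adjustment within that list. Where a list was described for a single library, its median was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. Those percentiles describe these libraries only. The counting interval of a ratio was exact (Clopper-Pearson, 95%) and, as for all counts without molecular identifiers, covers counting error only.

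The genes to be named were also set by a rule fixed before the data were examined. It took the 10 largest rises and the 10 largest falls among genes with an adjusted p below 0.05, an absolute log2 fold change of at least 1, groups that did not overlap and a mean of at least 10 CPM in the higher group, leaving out predicted genes. From each list it took up to 4 members with the smallest adjusted p below 0.05 and a mean of at least 5 CPM, or the 2 with the highest mean where none passed. Trp53, Cdkn1a, Mdm2, Kras, S100a8, S100a9, Fgfr1, Fgfr2, Fgf2, Mki67 and Ptgs2 were always included. The rule gave 136 genes, from which the text gives examples. Genes named outside it are said to have been chosen after their values were seen.

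The fits were tested on simulated counts drawn from the means and library sizes of this comparison. Both groups were given the same dispersion, unlike the real ones, and 200 of 14009 genes were changed. Of the changed genes, 52% of those with a 2-fold and 96% of those with a 4-fold change were recovered, and 11 of 159 calls were false. In the simulation, where genes vary independently, all 5 raised lists and 0 of 20 unchanged lists were called with the preset correlation. The estimated correlation was not simulated.

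The alternatives fixed in advance were median-of-ratios, upper-quartile and library-size scaling, no filter and a stricter one (5 CPM in 3 libraries), and DESeq2 (1.42.0) and limma-voom. They also included a replicate block, each library left out, an adjusted p threshold of 0.01, a test against a 1.5-fold change, and, for lists, an estimated correlation and fry. Alternatives for a table of normalised values did not apply. A fit without the 3 libraries that held neutrophil transcripts and a fit with the neutrophil markers' mean as a covariate were added after the data were seen. The first of these leaves 1 reactivated library, which is assumed to vary like the 2 parental ones. Figures were drawn with Python and matplotlib.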

Results

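The series measured polyadenylated transcripts in a mouse lung cancer cell line, called KPr in the labels. The cells carry mutant Kras, a Trp53 allele silenced by a removable transcriptional stop, and a tamoxifen-inducible Cre recombinase at Rosa26. The labels separate 3 libraries of parental cells from 3 libraries of reactivated cells, and the design text adds that the reactivation was by S100A8/9, a pair of calcium-binding proteins abundant in neutrophils. The comparison asks how the transcriptome of cells that had been woken from dormancy differs from that of the parental line. The groups also differed in Y-linked transcripts, as described below. A difference in clone, chromosome content or origin therefore cannot be separated from reactivation for any gene or list. Sequencing of transcript 3′ ends from 100 ng of total RNA per library gave 26087719, 24955652 and 28319564 counts in parental libraries 1 to 3, and 29441082, 26617484 and 27233922 counts in reactivated libraries 1 to 3. The table held 51789 genes, of which 24920 had at least 1 count and 14365 were tested. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. That spread was unequal, with a biological coefficient of variation of 35.3% among the parental libraries and 10.6% among the reactivated ones.

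Trp53 was read first in every library because the line carries a restorable allele. The allele's stop lies upstream of the 3′ end that was sequenced, so reads there depend on transcription through the stop. Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873, GRCm38) gave 21, 10 and 3659 counts in the libraries labelled parental 1, 2 and 3, and 34, 26 and 30 counts in reactivated 1, 2 and 3. In normalised units this was 0.841, 0.405 and 140.3 CPM (counts scaled per 1e+06) against 1.10, 0.944 and 1.05 CPM. The single high library set the parental mean of 47.2 ± 80.6 CPM (SD, n = 3), and the groups did not differ by edgeR's quasi-likelihood test (log2 fold change −5.51, adjusted p = 0.0764). Without the library labelled parental 3 the log2 fold change was 0.72 (edgeR adjusted p = 0.280). Without parental 1 or parental 2, the edgeR adjusted p was 0.0132 or 0.0479.

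Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases (chromosome 17, 29090976 to 29100727), was at 24.7, 9.55 and 86.1 CPM in the parental libraries and at 5.79, 5.55 and 6.72 CPM in the reactivated ones. It fell by 2.74 on the log2 scale (SE 0.72, edgeR adjusted p = 0.0267), and by 1.51 without the library labelled parental 3 (edgeR adjusted p = 0.0316). The call was lost when any reactivated library was left out (edgeR adjusted p = 0.0916, 0.109 and 0.0877 without reactivated 1, 2 and 3), without the 3 libraries that held neutrophil transcripts (0.128, at a log2 fold change of −2.81) and under limma-voom (adjusted p = 0.0809). Mdm2, the ubiquitin ligase that p53 induces (chromosome 10, 117688875 to 117710758), was at 63.6, 49.96 and 224.5 CPM in parental and 73.8, 81.1 and 72.1 CPM in reactivated libraries. Its groups did not differ (log2 fold change −0.57, edgeR adjusted p = 0.436), and the sign turned without the library labelled parental 3 (0.41, edgeR adjusted p = 0.0823). Of 32 measured p53 targets, 2 rose and 6 fell, the same numbers when adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.431). Plk2, a kinase of the stress response, fell from 111.9 ± 21.2 to 30.1 ± 1.7 CPM (SD, n = 3, edgeR adjusted p = 6.54e-04). Where results below involve this library, the group names stand for the labels.

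**Figure D1:**
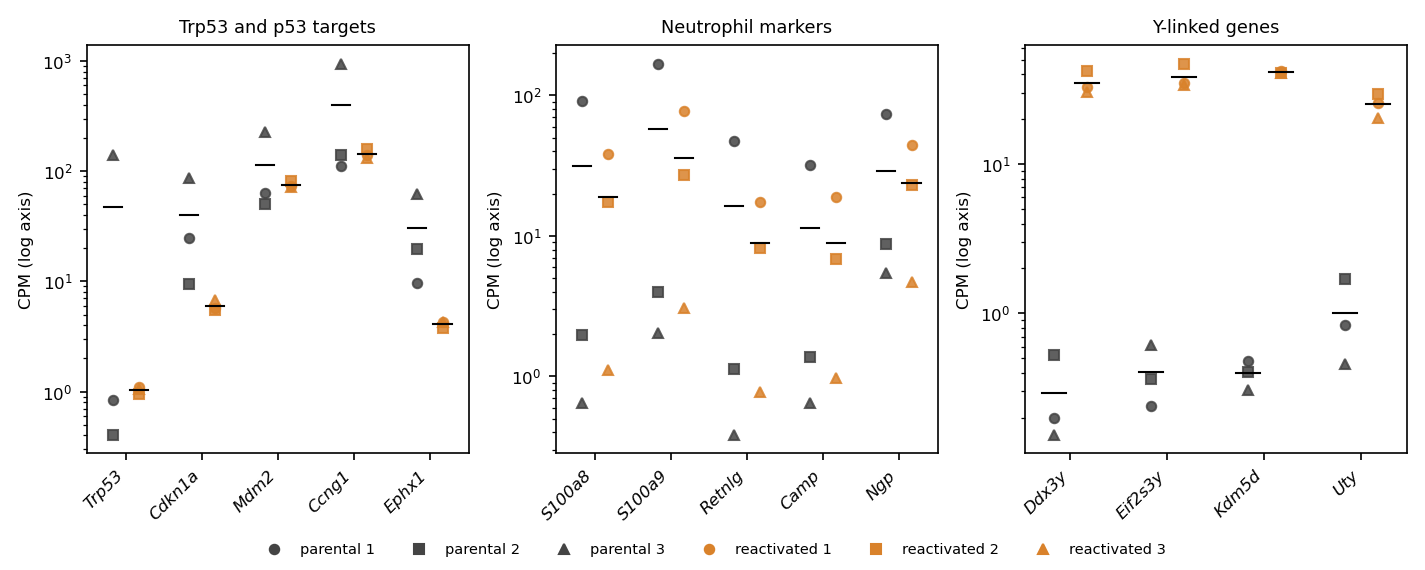
Level of Trp53 and 4 p53 targets, 5 neutrophil markers and 4 Y-linked genes in each of the 6 libraries, in CPM on a log axis. Each symbol is 1 library and each bar the mean of 3. Trp53 stands at 140.3 CPM in parental 3 and at 1.10 CPM or less in the other 5 libraries, neutrophil markers are high in parental 1, reactivated 1 and reactivated 2, and these 4 Y-linked genes separate the groups.

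Among the named genes, the largest falls in reactivated cells were in genes of cell division. The largest rises were in genes almost silent in parental cells, which a ranking by fold change favours. Mki67, a marker of cycling cells (chromosome 7, 135689784 to 135716361), was at 814.4 ± 396 CPM in parental and 45.2 ± 0.16 CPM in reactivated libraries (SD, n = 3), 18.0-fold lower (edgeR adjusted p = 9.34e-04). Thbd, which encodes the endothelial anticoagulant receptor thrombomodulin (chromosome 2, 148404466 to 148408188), was at 0.286 ± 0.258 CPM in parental and 108.6 ± 5.1 CPM in reactivated libraries (log2 fold change 8.53, and 9.54 without parental 3, SE 0.43, edgeR adjusted p = 1.64e-04). In all, 4395 of 14365 genes changed by edgeR's quasi-likelihood test, 2055 higher and 2340 lower in reactivated cells. At least 2-fold changes made up 1106 of the rises and 1059 of the falls, and at least 8-fold changes 304 and 161. The groups did not overlap in 7108 genes, 49.5% of those tested, where 10% is the share that chance gives for 3 against 3. Of the 4395 calls, 4373 were among them.

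The count depended on single libraries. It was 7326, 3311 and 3854 without parental 1, 2 and 3, and 1821, 2069 and 1998 without reactivated 1, 2 and 3. Without the 3 libraries that held neutrophil transcripts (parental 1, reactivated 1 and reactivated 2; an alternative added after the data were seen), which leaves 1 reactivated library, it was 1934. The balance of directions depended on scaling: upper-quartile scaling moved all log2 fold changes up by a median of 0.13 and called 2659 genes higher and 1791 lower (59.8% higher, against 46.8%), and scaling to library size alone called 2657 and 1784.

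The 10 named genes with the largest rises had log2 fold changes from 6.69 to 9.65, and each was still called when any single library was left out (highest edgeR adjusted p = 0.0106). Slc5a7, the choline transporter of cholinergic neurons (chromosome 17, 54273590 to 54299034), had 1 count in the parental libraries together and 1242 in the reactivated ones, a ratio of 1081 with a 95% counting interval of 194 to 42748. Prl, which encodes the pituitary hormone prolactin (chromosome 13, 27057570 to 27065205), was at 0.542 ± 0.661 CPM and 107.6 ± 2.3 CPM (log2 fold change 7.60, SE 0.64, edgeR adjusted p = 6.02e-04). Scarf2, a scavenger receptor of the cell surface, rose by 8.34 on the log2 scale. Slc13a4, a sulphate transporter, rose by 8.02, Lrrn1, a leucine-rich repeat protein, by 7.90, and Zfp422, a zinc finger protein, by 7.58. Myo5c, an unconventional myosin, rose by 7.2. The remaining 2 were Y-linked. Ddx3y, an RNA helicase (chromosome Y, 1260771 to 1286629), was at 0.293 ± 0.203 CPM in parental and 35.2 ± 6.0 CPM in reactivated libraries. Kdm5d, a histone demethylase (chromosome Y, 897788 to 956786), was at 0.397 ± 0.087 and 41.3 ± 0.71 CPM (log2 fold change 6.69, SE 0.21, edgeR adjusted p = 3.93e-05). Low parental counts leave the size of these rises uncertain. Leaving out 1 parental library raised the fold change by over 1.5 times for Slc5a7 (log2 fold change 11.6 without parental 2), Prl (9.34 without parental 3, which held 34 of its 42 parental counts), Slc13a4 (8.72 without parental 1), Lrrn1 (8.49 without parental 2), Zfp422 (9.09 without parental 1), Myo5c (8.20 without parental 3) and Ddx3y (7.58 without parental 2). Ddx3y and Kdm5d have a related copy on the X chromosome, and Ddx3y overlaps predicted genes, so reads can be shared. Their X-linked homologues, named after the values were seen, were at 321.2 ± 30.6 and 224.7 ± 17 CPM for Ddx3x and at 45.4 ± 2.0 and 69.6 ± 2.3 CPM for Kdm5c.

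All 10 named genes with the largest falls take part in or follow cell division. Their log2 fold changes ran from −5.03 to −4.30, and each was called without any single library (highest edgeR adjusted p = 0.0258). Pclaf, a partner of the replication clamp (chromosome 9, 65890237 to 65903266), fell from 332.4 ± 176 to 10.1 ± 1.4 CPM, 32.8-fold (edgeR adjusted p = 8.81e-04), and overlaps Trip4. Birc5, the mitotic protein survivin (chromosome 11, 117849251 to 117855743), was 27.2-fold lower, and the kinetochore genes Ska1 and Nuf2 were 26.6-fold and 26.2-fold lower. Ccna2, which encodes cyclin A2 and overlaps Exosc9, was 22.4-fold lower, the mitotic kinase gene Pbk 22.1-fold and the spindle motor gene Kif15 20.98-fold (log2 fold change −4.39, and −5.01 without the 3 libraries that held neutrophil transcripts). Rrm2, a subunit of ribonucleotide reductase, was 20.3-fold lower, and Sapcd2, which orients the spindle, and Mybl2, a transcription factor of cycling cells, were both 19.8-fold lower.

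**Figure D2:**
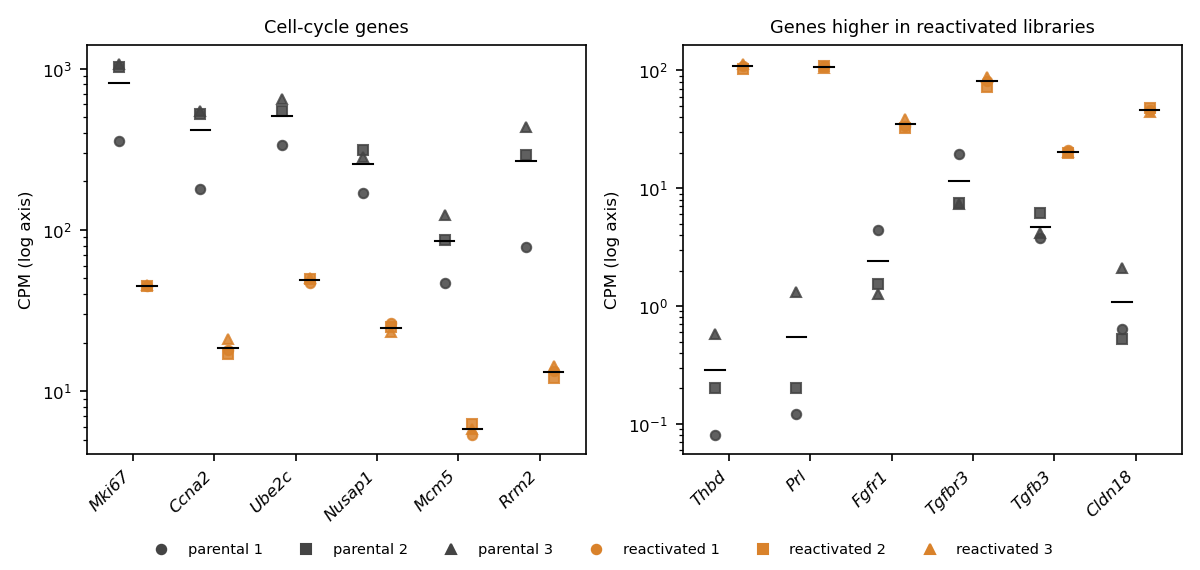
Level of 6 cell-cycle genes and of 6 genes higher in reactivated libraries, in CPM on a log axis, for each of the 6 libraries. Each symbol is 1 library and each bar the mean of 3. Mki67 averages 814.4 CPM in parental and 45.2 CPM in reactivated libraries, and Thbd 0.286 and 108.6 CPM.

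Among 31 gene lists with at least 5 measured members, 9 were called by camera with a preset correlation of 0.01, 8 of them lower and 1 higher in reactivated cells. None was called with an estimated correlation, where the lowest adjusted p was 0.591 and 0 lists had an unadjusted p under 0.05. That setting was not tried on simulated counts, so whether it could call a changed list in 6 libraries is unknown. The dormancy list lost its call at an estimated correlation of 0.026, near the preset 0.01. Correlation between genes alone therefore does not account for the lack of calls. The self-contained test fry called 10. With the preset correlation, camera called between 7 and 15 lists in the other 9 splits of the 6 libraries into 3 and 3. In each of those splits edgeR called 0 genes, with 56 to 760 genes at an unadjusted p under 0.05. Those splits mix both groups on each side, so part of the group difference remains in them. The calls there therefore do not measure how often either test calls wrongly.

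All 36 measured genes of G2/M and mitosis fell, over all genes and adjusted over the list alone, with a median log2 fold change of −3.41, a 10.6-fold lower level (camera adjusted p = 1.15e-22; adjusted p = 0.591 with an estimated correlation). Nusap1, which bundles spindle microtubules and overlaps Oip5, fell from 255.1 ± 75.0 to 24.8 ± 1.5 CPM (SD, n = 3), and Ube2c, which primes cyclins for degradation, from 508.4 ± 159 to 48.9 ± 2.0 CPM. Of 40 genes of G1/S and DNA replication, 39 fell, 40 adjusted over the list alone, and the median was −2.33 (camera adjusted p = 3.03e-16; adjusted p = 0.687 with an estimated correlation). The helicase subunit gene Mcm5 fell 14.7-fold, the replication initiator Mcm10 12.7-fold and the primase gene Prim1 6.98-fold. The parental libraries differed among themselves in the same genes: parental 1 lay below the other parental libraries by a median log2 difference of −1.26 in the mitotic list and −1.38 in the replication list. In parental 1 itself, Mki67 was at 357.5 CPM, against at most 45.4 CPM in any reactivated library.

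Lists of biosynthesis and mitochondrial energy supply were lower by smaller steps. Of 35 genes of oxidative phosphorylation, 24 fell (27 adjusted over the list alone) and none rose, with a median log2 fold change of −0.59 (camera adjusted p = 9.93e-08; adjusted p = 0.591 with an estimated correlation). Cox5b, a subunit of cytochrome c oxidase, fell from 445.9 ± 21.4 to 243.6 ± 14.5 CPM, a call lost without the 3 libraries that held neutrophil transcripts (edgeR adjusted p = 0.0714) at a log2 fold change of −0.77, against −0.87 with all libraries. Of 31 MYC targets in ribosome biogenesis, 17 fell (19 adjusted over the list alone), with a median of −0.63 (camera adjusted p = 1.24e-05; adjusted p = 0.941 with an estimated correlation). The gene of nucleolin, Ncl, fell from 2064 ± 506 to 871.3 ± 77.3 CPM, and Nop58, of the small nucleolar ribonucleoprotein core, fell 2.13-fold. Of 26 genes of cholesterol synthesis, 12 fell and 1 rose (17 and 1 adjusted over the list alone), with a median of −0.74 (camera adjusted p = 5.27e-04; adjusted p = 0.974 with an estimated correlation). Stard4, a sterol carrier, fell 2.61-fold and the lipoprotein receptor gene Ldlr 2.01-fold. In the cholesterol list parental 1 lay below the other parental libraries by a median log2 difference of −0.58.

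Of 20 endoplasmic reticulum chaperones, 9 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of −0.57 (camera adjusted p = 0.00324; adjusted p = 0.591 with an estimated correlation). Hspa5, the main chaperone of the compartment, fell from 1272 ± 300 to 537.6 ± 28.0 CPM. Of 29 NRF2 targets, 10 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of −0.51 (camera adjusted p = 0.00869; adjusted p = 0.733 with an estimated correlation). Aldh3a1, an aldehyde dehydrogenase, fell 5.11-fold, and Gsr, glutathione reductase, fell from 326.5 ± 52.9 to 116.5 ± 0.88 CPM. None of these 5 lists was lost when a single library was left out.

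Of 12 measured genes of the S100 family, 8 fell and none rose (9 and 0 adjusted over the list alone), with a median log2 fold change of −1.27 (camera adjusted p = 0.00376; adjusted p = 0.591 with an estimated correlation). S100a10, the annexin A2 partner, fell from 1036 ± 347 to 282.0 ± 6.4 CPM, and S100a4 from 198.7 ± 111 to 35.1 ± 3.0 CPM. Within the parental group, parental 1 lay below the other libraries in this list by a median log2 difference of −0.80. The family's members resemble one another, so shared reads cannot be ruled out. S100a8 and S100a9, which encode the proteins named in the design text, did not follow the groups. S100a8 (chromosome 3, 90668978 to 90670035) was at 91.5, 1.98 and 0.652 CPM in parental 1 to 3 and at 38.1, 17.3 and 1.12 CPM in reactivated 1 to 3 (log2 fold change −0.73, edgeR adjusted p = 0.765). S100a9 was at 167.3, 3.96 and 2.03 CPM and at 78.1, 27.0 and 3.05 CPM (log2 fold change −0.68, edgeR adjusted p = 0.774). Without parental 1 both were called higher in reactivated cells, by 3.86 (edgeR adjusted p = 0.0349) and 3.61 (edgeR adjusted p = 0.0329). Summed over 15 neutrophil markers, the level was 496.1, 26.5 and 17.1 CPM in parental 1 to 3 and 239.8, 120.5 and 16.2 CPM in reactivated 1 to 3. None of the 15 changed between the groups by edgeR, also when adjusted over the list alone and with 0 at an unadjusted p under 0.05, and the list was not called (camera adjusted p = 0.946). Of 13 pan-leukocyte and macrophage markers 1 rose, 0 adjusted over the list alone (camera adjusted p = 0.612). Lyz2, lysozyme of macrophages, neutrophils and alveolar cells, was at 18.7 ± 28.4 and 14.5 ± 14.4 CPM (log2 fold change −0.36, and 2.70 without parental 1 with an edgeR adjusted p of 0.0612).

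One list was higher. Of 27 dormancy-associated genes, 11 rose and 3 fell (12 and 3 adjusted over the list alone), with a median log2 fold change of 0.67 (camera adjusted p = 0.00765; adjusted p = 0.591 with an estimated correlation). Tgfbr3, the TGF-beta co-receptor betaglycan, rose from 11.4 ± 7.0 to 81.0 ± 7.6 CPM (7.08-fold, edgeR adjusted p = 0.00281; log2 fold change 2.82, and 3.46 without parental 1), and Tgfb3, one of its ligands, from 4.70 ± 1.30 to 20.4 ± 0.62 CPM (4.33-fold, edgeR adjusted p = 0.00116). Both genes overlap others, Tgfb3 with Ttll5. Thbs1, Bmp7 and Gas6, list members named after their values were seen, also rose, Thbs1 2.61-fold and Bmp7 3.14-fold. Gas6, with 3, 0 and 1 counts in the parental libraries, was at 0.053 ± 0.061 and 2.87 ± 0.16 CPM, and its log2 fold change of 5.64 ranged from 5.09 to 6.90 with 1 library left out. In the same list parental 1 lay above the other parental libraries by a median log2 difference of 0.40.

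Of 17 genes for FGF ligands, receptors and binding proteins, 6 rose and 3 fell (7 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0693, and 0.0287 without parental 2). Fgfr1 (chromosome 8, 25513654 to 25575718) rose from 2.40 ± 1.74 to 35.0 ± 3.5 CPM (log2 fold change 3.86, SE 0.46, edgeR adjusted p = 0.00174). Parental 1, at 4.41 CPM against 1.54 and 1.27, set the parental mean, and without it the log2 fold change was 4.66, and 4.81 without the 3 libraries that held neutrophil transcripts. The decoy receptor gene Fgfrl1 rose 2.21-fold, while Fgf13 and the heparan sulphate proteoglycan gene Gpc1 fell 2.17-fold and 2.58-fold. Fgf2, which overlaps the antisense gene Nudt6, rose from 4.01 ± 1.46 to 10.9 ± 0.64 CPM (edgeR adjusted p = 0.00846), a call lost without the 3 libraries that held neutrophil transcripts (edgeR adjusted p = 0.106) at a log2 fold change of 1.30, against 1.44 with all libraries. Fgfr2 was at 0.764 ± 0.680 and 2.85 ± 0.36 CPM and missed the threshold (edgeR adjusted p = 0.0609). Its log2 fold change was 1.90, and from 1.41 to 2.81 with 1 library left out. It was called without parental 2 (edgeR adjusted p = 0.0245), with no filter (0.0411), with the neutrophil covariate, added after the data were seen (0.0421), by DESeq2 (adjusted p = 0.0119) and by limma-voom (adjusted p = 0.0259). Kras was at 102.1 ± 14.1 and 138.1 ± 16 CPM (edgeR adjusted p = 0.0602). It was called without parental 1 (edgeR adjusted p = 0.00714), under upper-quartile (0.0299) and library-size scaling (0.0226), with the stricter filter (0.0412) and with the covariate (0.0409). Ptgs2, the inducible cyclooxygenase, fell from 540.0 ± 200 to 222.3 ± 13 CPM (2.43-fold, edgeR adjusted p = 0.00895).

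The remaining lists were not called as wholes, and several held members that moved strongly. Of 21 senescence-associated secreted factors, 4 rose and 4 fell, 4 and 5 adjusted over the list alone (camera adjusted p = 0.770). Those that rose included the matrix metalloproteinase genes Mmp3, from 1.91 ± 0.98 to 80.7 ± 1.9 CPM, Mmp10, from 0.547 ± 0.390 to 27.3 ± 0.75 CPM, and Mmp13, from 11.5 ± 9.9 to 265.1 ± 12.8 CPM. The log2 fold change of Mmp10 was 5.62, and 6.38 without parental 3, and that of Mmp13 4.53, and 5.51 without parental 1. Among the falls was Serpine1, an inhibitor of plasminogen activation, which was 3.29-fold lower. Of 30 mesenchymal and extracellular matrix genes, 8 rose and 7 fell (camera adjusted p = 0.478), with Twist1 3.18-fold and Col6a1 4.13-fold higher and Loxl2 3.47-fold lower. Of 25 epithelial genes, 3 rose and 6 fell (camera adjusted p = 0.962). Krt19 fell from 731.8 ± 15.4 to 280.3 ± 16.4 CPM, Cldn6 4.14-fold and Elf3 8.18-fold. Epcam, named after its values were seen, rose from 0.473 ± 0.377 to 4.30 ± 0.38 CPM (edgeR adjusted p = 0.0125), a call lost without reactivated 2 or reactivated 3 (edgeR adjusted p = 0.0609 and 0.0529). Of 17 lung lineage genes, which include Lyz2, 4 rose and 1 fell (camera adjusted p = 0.600). The alveolar claudin Cldn18 rose from 1.09 ± 0.88 to 46.3 ± 1.9 CPM (log2 fold change 5.39, and 6.30 without parental 3), and Foxa1 1.96-fold. Of 22 TGF-beta targets, 7 rose and 3 fell, 8 and 3 adjusted over the list alone (camera adjusted p = 0.313), with Ltbp3 2.05-fold higher. Of 21 YAP targets, 4 rose and 4 fell (camera adjusted p = 0.946), with Dock5 and F3 2.00-fold and 2.52-fold lower.

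Of 25 genes of the NF-kB and inflammatory response, 7 fell and none rose (median log2 fold change −1.04, camera adjusted p = 0.146). The call was gained without the library labelled parental 3, which lay below the other parental libraries by a median of −0.75 (camera adjusted p = 5.84e-06). Sod2, mitochondrial superoxide dismutase, fell from 99.7 ± 1.3 to 48.3 ± 2.2 CPM. Of 30 genes of the integrated stress response, 2 fell, 0 adjusted over the list alone, and the median log2 fold change was 0.12 (camera adjusted p = 0.603). This list was higher without parental 1, which lay above the other parental libraries by a median of 1.35 (camera adjusted p = 1.27e-04). Of 20 heat shock genes, 7 fell and 1 rose (camera adjusted p = 0.146, and 0.0202 without parental 1), with Stip1 1.92-fold lower. Of 19 interferon response genes, 3 rose and 2 fell (camera adjusted p = 0.208, and 0.0317 without parental 2), with Irgm1 2.23-fold higher. Of 29 genes of glycolysis and the hypoxia response, 7 fell and none rose (camera adjusted p = 0.276), among them Ldha, from 1184 ± 208 to 509.2 ± 12.7 CPM.

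Of 24 genes of ERK pathway output, 5 rose and 6 fell, 5 and 8 adjusted over the list alone (camera adjusted p = 0.770). Fosl1 was 2.66-fold and Ccnd1 2.13-fold lower. Of 14 MHC class I genes, 2 rose and 2 fell (camera adjusted p = 0.603), with B2m 2.00-fold higher. Of 20 eicosanoid and oxidised lipid genes, 3 rose and 3 fell (camera adjusted p = 0.823), with Ptges, which makes prostaglandin E from the cyclooxygenase product, 6.34-fold higher (log2 fold change 2.66, and 3.31 without parental 3). In fatty acid synthesis and storage 2 of 22 genes rose and 3 fell (camera adjusted p = 0.689). Among cAMP/CREB and immediate early genes 1 of 23 rose and 3 fell, 1 and 1 adjusted over the list alone (camera adjusted p = 0.600). Of 37 ribosomal protein genes, 4 fell, 2 adjusted over the list alone (camera adjusted p = 0.770). Among 6 endothelial markers 2 rose and 1 fell (camera adjusted p = 0.689). Of the fibroblast markers only 4 were measured, too few for the test, and 1 rose: Pdgfra, from 0.212 ± 0.027 to 2.76 ± 0.52 CPM. Adjusted over the list alone, 1 rose and 1 fell. The median and the mean of the log2 fold changes differed in sign for the epithelial, lung lineage, senescence, eicosanoid, heat shock and YAP lists. The camera direction differed from both in the neutrophil and pan-leukocyte lists.

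**Figure D3:**
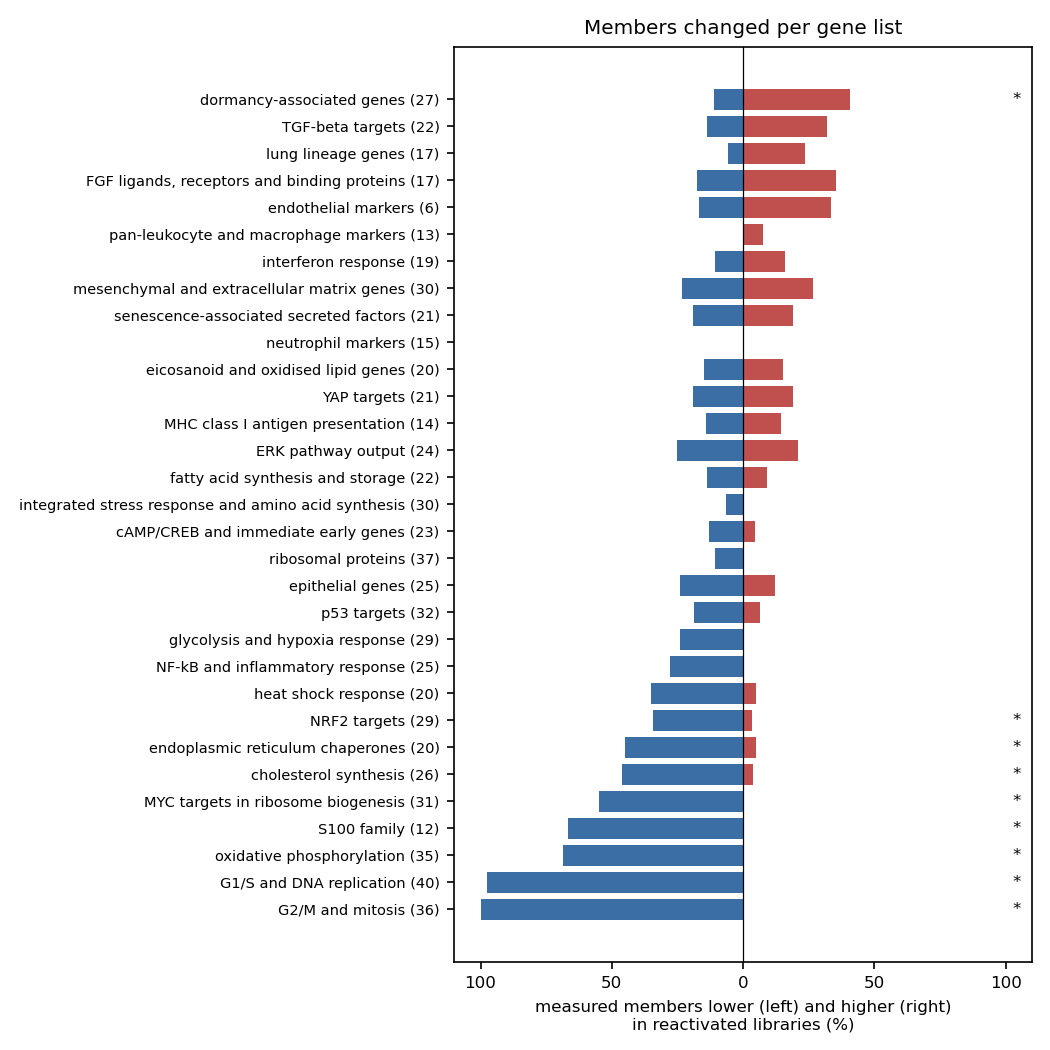
Percentage of the measured members of each of 31 gene lists that were lower (left) or higher (right) in reactivated libraries at an edgeR adjusted p under 0.05, with the number measured in parentheses. Asterisks mark the 9 lists called by camera with a preset correlation. None of them was called with an estimated correlation, a setting not tried on simulated counts. All 36 genes of G2/M and mitosis were lower, and 11 of 27 dormancy-associated genes were higher.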

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

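The settings without the 3 libraries that held neutrophil transcripts and with the neutrophil covariate were chosen after the data were seen. The number of changed genes, 4395 (2055 higher, 2340 lower), stayed within 1.5 times under other scalings, filters, DESeq2 (5110, with 7761 genes given no adjusted p), limma-voom (4446) and the covariate (5195). It was 1820 (830, 990) at an adjusted p of 0.01, 1473 (716, 757) against a 1.5-fold change, and 1934 (876, 1058) without the 3 libraries. Leaving out 1 library gave from 1821 (811, 1010; without reactivated 1) to 7326 (3630, 3696; without parental 1). No setting gave any of the 4395 genes a call in the opposite direction. The replicate numbers were not taken as pairs, since the labels do not say that equal numbers share a culture or day. In the data, deviations of same-numbered libraries correlated at 0.22, 0.01 and 0.21 across genes. Libraries 1 and 3 of each group matched their own number best, and libraries 2 another, a hint from the data only. With the number as a block, 3467 genes (1663, 1804) were called. The causes of these differences were not tested.

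All 9 lists were called under each scaling and filter, with each library left out, under the block and in both added settings. With an estimated correlation 0 were called, and fry, which asks only whether a list's genes move one way, called 10, without cholesterol synthesis (adjusted p = 0.148) and MYC targets (0.0932). It added the FGF list (0.00703) and the lung lineage and mesenchymal lists (both 0.0243). The block called the FGF list (0.0480), dropping the filter called NF-kB (0.0327), and leaving out the 3 libraries called the integrated stress response (6.59e-05). Trp53 had a log2 fold change of −5.51 (adjusted p = 0.0764), −5.51 (0.0347) with no filter, and from −6.09 to 0.72 with 1 library left out, called without parental 1 or parental 2. It was −1.93 under the block, −1.88 by limma-voom and −3.36 with the covariate, not called. The stricter filter removed it and DESeq2 gave it no adjusted p. With 1 library left out, S100a8 ranged from −1.80 to 3.86 and S100a9 from −1.98 to 3.61, both called only without parental 1; limma-voom (0.92 and 0.79), the block, the covariate and, for S100a9, leaving out the 3 libraries gave positive values, not called. Of 126 named genes that were called, 96 kept their call in all 6 fits that left out 1 library and 85 without the 3 libraries. The cause of these losses was not tested. The simulation recovered 52% of 2-fold changes, with 200 of 14009 genes changed and the same spread in both groups. The real groups differed in spread, and 4395 of 14365 genes were called. This share therefore does not carry over to the real test, where small changes may still be missed.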

Other observations

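The tests of explanations in this part were chosen after the values were seen, except the counts over other splits of the libraries. So were all genes named in this part other than Trp53, Mki67, S100a8, S100a9, Ngp, Prl, Ddx3y and Kdm5d. The parental libraries differed from one another in whole gene groups, each described here from 1 library with no test. Parental 1 lay above the other parental libraries in the integrated stress response (median log2 difference 1.35) and in glycolysis and hypoxia response genes (0.64), both above all 10000 random lists matched on expression. Ddit3, a transcription factor of that stress response, was at 153.5, 10.4 and 8.93 CPM in parental 1, 2 and 3, Trib3 at 113.7, 10.4 and 6.63 CPM, and the hypoxia gene Ero1l at 1300, 175.4 and 172.5 CPM. The library labelled parental 3 lay below the others in NF-kB genes (−0.75) and above them in MYC targets (0.62). Cxcl5, a chemokine that attracts neutrophils, was at 24.8, 34.7 and 0.498 CPM in parental 1, 2 and 3.

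Prl rose by 7.60 on the log2 scale. Prl2c2, a proliferin gene with near-identical copies, fell from 585.0 ± 431 to 67.4 ± 7.9 CPM (SD, n = 3, edgeR adjusted p = 0.00528; log2 fold change −3.12, and −2.36 without parental 3), and the related Prl2c3 was not called (32.2 ± 34.6 and 8.13 ± 1.64 CPM, edgeR adjusted p = 0.0824). The surface antigen genes Ly6a and Ly6c1 rose from 16.2 ± 10.4 to 101.7 ± 5.2 CPM and from 5.32 ± 3.19 to 42.7 ± 2.7 CPM. Clu, which encodes the chaperone clusterin, rose from 1384 ± 621 to 4705 ± 420 CPM, and Vim, vimentin, fell from 7194 ± 2222 to 3009 ± 168 CPM.

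The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. All but the real one mix the groups and keep part of their difference, so they do not show what unrelated libraries would give. For genes, 1 of the 10, the real one with 4395, gave as many calls, and the highest of the others was 0 by edgeR, with 56 to 760 genes at an unadjusted p under 0.05. For gene lists, 9 of the 10 gave at least the 9 lists of the real split, and the highest of the others was 15.

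Neutrophil transcripts were present in parental 1, reactivated 1 and reactivated 2, at a summed 496.1, 239.8 and 120.5 CPM over 15 markers, against 16.2 to 26.5 CPM elsewhere. Expression of S100a8 and S100a9 by the tumour cells alone is argued against, because 84.6% of the other 13 markers, among them Retnlg, Camp, Ngp and Ly6g, were over 4-fold higher in parental 1 than in both other parental libraries. RNA from neutrophils is a candidate source. The log2 ratio of reactivated 1 to parental 1, less the background, was taken over 14 markers. Its SD was 0.46 around a median ratio of 45.2%, as a source of the same composition in these 2 libraries would give. The spread of this ratio was not tested for reactivated 2. There Ltf was higher than in parental 1 (18.2 against 8.29 CPM). Each other marker was lower there, such as S100a8 (17.3 against 91.5 CPM). A single source of fixed composition is therefore not shown for all 3 libraries. Reads of a neutrophil library assigned to these libraries during sequencing would keep the same ratio of reactivated 1 to parental 1 (SD 0.46). Such reads cannot be told apart from neutrophil RNA. The groups do not follow these transcripts, since parental 1 held the most and reactivated 3 the least.

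Trp53 transcript at 140.3 CPM in the library labelled parental 3 alone came with higher p53 targets. Their median, without Trp53 itself, was 0.72 above the other parental libraries on the log2 scale and above all 10000 random lists. Ccng1 was at 937.7 against 112.6 and 139.2 CPM. The rank is not particular to p53 targets. In the same library the replication (0.86), mitotic (0.71), MYC target (0.62) and heat shock (0.50) lists also lay above all random lists. Parental 1, part of that comparison, lay below the other parental libraries in these lists, by medians of −1.38, −1.26, −0.34 and −0.43. In p53 targets its median was −0.46. Part of each rank may therefore reflect a low parental 1 rather than a high parental 3. Transcript of Trp53 itself was thus read in that library. Active p53 in that culture is a candidate explanation for the higher targets, which the rank alone cannot decide. Admixture of, or exchange with, a reactivated library is argued against by the highest Trp53 level there, 1.10 CPM. Whether the allele had been recombined on purpose, or the library belongs to another culture, stays open and was not tested. Mki67 in the same library was at 1067 CPM, the highest of the 6, near the 1018 CPM of parental 2 and above the 357.5 CPM of parental 1.

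The male-specific genes Ddx3y, Kdm5d, Eif2s3y and Uty summed to 2.10 ± 0.79 CPM in parental and 140.4 ± 17.5 CPM in reactivated libraries. The 4 other measured genes placed on the Y chromosome, all predicted genes, differed less: Gm37158 and Gm47283 were higher in every reactivated library than in any parental one, by smaller folds, and Gm20826 and Gm21742 overlapped between the groups. Gm20826 was at 4.23 ± 1.08 and 5.02 ± 0.80 CPM (edgeR adjusted p = 0.501), Gm37158 at 19.4 ± 9.2 and 35.8 ± 4.0 CPM (0.0744), Gm47283 at 38.6 ± 10.7 and 80.1 ± 9.6 CPM (0.0101) and Gm21742 at 0.281 ± 0.214 and 0.341 ± 0.138 CPM (0.800). Whether their reads come from the Y chromosome or from similar sequences elsewhere was not tested. For the 4 named first, reads shared with the X-linked homologues are argued against, because the lowest parental to reactivated ratio of a homologue was 0.54, for Kdm6a. The neutrophils are argued against too: the summed level in reactivated 1 was 1.09 times that in reactivated 3, where the neutrophil markers differed 14.8-fold. Medians of the log2 fold change per chromosome ranged over 0.64, from −0.42 on chromosome 14 to 0.22 on X, beyond the 0.19 of shuffled genes. The difference between 2 parental libraries, parental 3 and parental 2, ranged over 0.38. That difference was not shuffled itself, and parental 3 may belong to another culture. The test therefore cannot tell copy number apart from expression. The criteria of this last test were rewritten after its value was seen, and 1 further test, which used the Y-linked genes that form the pattern, was run and dropped because it could not have failed. Loss of the Y chromosome, or of the part with these 4 genes, from the parental culture, a clone grown out on reactivation, or cells of another origin may each underlie the pattern and were not tested. Such a difference between the groups could also contribute to the other genes and lists that changed.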
